A study of Mus musculus with 6 samples.

How the data were processed

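Peak lists of 6 CUT&RUN libraries from gastrocnemius muscle of 4-week-old male mice were used: H3K4me3 in Ctrl, H3K9me2 in Ctrl and in CKO, 2 inputs in Ctrl and 1 input in CKO. Groups follow the labels' titles and genotypes. The H3K4me3 library is titled wild type, and its genotype label is Ctrl with floxed Phf2 and no Cre, per the labels. How the input was prepared, and whether an input served as control in peak calling, is not given in the sources used here. Nor is it said whether the libraries came from separate animals.

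Reads were aligned with Bowtie2 to mm10 and peaks called with MACS2, per the submitters' processing notes, and the versions are not given in the sources used here. The deposited lists are 1 per library and name no pooling. For each peak the authors gave its position, a fold (the ratio of summit pileup to local background), a −log10 p-value, a −log10 q-value, a score and an offset. The score the authors deposited is 10 times −log10 q, rounded down to a whole number. The deposited offset gives the summit's distance from the peak start in bp and was used for no value here. The lowest −log10 q in each list was close to 1.3, so the lists appear to stop at q of 0.05. H3K9me2 often lies in broad domains, and these lists hold narrow peaks. Merging peaks within 1 kb left 12796 of 12832 in CKO and 3698 of 3703 in Ctrl.

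Peaks on chromosomes 1 to 19, X and Y were used, 16573 of 16608 for H3K4me3, 3703 of 3726 and 12832 of 12891 for H3K9me2 in Ctrl and CKO, 3071 of 3117 and 1309 of 1347 for the Ctrl inputs and 10931 of 10997 for the CKO input. Overlap meant 1 bp or more. Shares carry exact 95% binomial intervals (Clopper-Pearson), which cover counting error alone: peaks are not replicate animals. Chance overlap came from 1000 placements of the peaks at random within their chromosomes at unchanged length, seed 7, from position 3000000 to the last position seen. It takes no account of unmappable or repetitive sequence.

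Depth was read from the peaks themselves. The fold equals summit fragments plus 1 over local background plus 1, and the p-value is the upper tail of a Poisson distribution. Together they gave whole fragment counts, with the listed −log10 p matched within 0.1%, for 98.6% to 99.96% of the peaks of each list. The lowest local background in a list is the genome-wide coverage of that library. On simulated peaks, overlap, chance overlap and fragment counts were recovered: 1500 of 1500 overlaps, a mean chance overlap of 103.5 where 104 was due, and 100% of 5000 fragment counts.

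Genes came from the RefSeq table of GRCm38.p6, the assembly mm10 is based on, with 21887 protein-coding genes on these chromosomes. The table used here gives gene start and end but neither strand nor exons. The promoter, exon and intron classes planned were therefore replaced by 3: peak centre within 2 kb of either gene end, in the gene body, or intergenic. A gene counted as marked by H3K4me3 with a peak within 2 kb of either end, and by H3K9me2 with an input-free peak in its body or within 2 kb of it.

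The comparisons, the 23 gene lists and the rule for named genes were fixed before the data were examined. The lists covered sarcomere genes (fast, slow and shared), myogenic regulators, atrophy and autophagy, oxidative metabolism, glycolysis, the neuromuscular junction and growth signalling. They also covered markers of satellite, fibroadipogenic, endothelial, blood and immune, adipocyte and Schwann cells, and enzymes, readers and cofactors of H3K9 and H3K4 methylation. The others were housekeeping, neuronal and liver genes, imprinted genes (10 of 14 among the protein-coding genes), olfactory receptors, vomeronasal receptors and numbered Zfp genes. Each list's count was placed among 10000 random lists of the same size, each gene being replaced by 1 of its 200 nearest in length. A list stood apart if at most 2.5% of random lists were as high or as low. These percentiles describe single libraries and test nothing between genotypes.

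The rule named Phf2, the 15 highest peaks of CKO alone, the 10 highest of Ctrl alone and the 10 highest shared by fold after removal of input peaks, the 10 highest H3K4me3 genes, up to 4 genes per list and mark, and the 5 highest regions per input. Examples are drawn from these, and a gene the rule would name is not reported here. Genes with an H3K9me2 peak in the body but not at an end were added to the examples after their values were seen, as was Kdm4c.

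Correlations over the 19 autosomes used 100000 permutations. Intergenic sequence was what lay outside protein-coding genes and 2 kb either side, and a peak was placed by its centre. Alternatives were peaks at or above the median fold of their list, q of 1e-05 or less, overlap of 50% of the shorter peak or within 1 kb, other removal of input peaks, leaving out either Ctrl input, all sequences, merged peaks, lists of equal length and windows of 1 and 5 kb. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.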

Results

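Histone marks were mapped by CUT&RUN, in which an antibody-tethered nuclease releases the DNA around a marked nucleosome, in gastrocnemius muscle of 4-week-old male mice. PHF2 is a JmjC-domain protein described as a demethylase of H3K9me2, a repressive mark, and its PHD finger binds H3K4me3, a mark of active promoters. The study examined its role in skeletal muscle. Control mice (Ctrl) carried floxed Phf2 alleles without Cre, and conditional knockout mice (CKO) carried the same alleles with Cre under the skeletal muscle actin promoter, Acta1. There were 6 peak lists from 6 libraries: 1 for H3K4me3 in Ctrl, 1 each for H3K9me2 in Ctrl and CKO, 2 for input in Ctrl and 1 for input in CKO. The H3K4me3 library is titled wild type, and its genotype label is that of Ctrl. With 1 H3K9me2 library per genotype, no difference between genotypes has a replicate check, and no test between genotypes was made. Folds given for peaks are the authors' own enrichment over local background, and all coordinates are mm10.

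The H3K4me3 list held 16573 peaks on chromosomes 1 to 19, X and Y, with a median width of 753 bp, a median fold of 10 and a median of 52 fragments at the summit. The H3K9me2 lists held 3703 peaks in Ctrl and 12832 in CKO, which were narrower (medians of 388 and 389 bp) and lower (median folds of 4.91 and 5.42). Their summits rested on medians of 6 fragments in Ctrl and 9 in CKO, so a single H3K9me2 peak is a small count. The input lists held 3071 and 1309 peaks in Ctrl and 10931 in CKO. Genome-wide background coverage, a measure of relative depth read from the peak values, was 0.391 fragments per position for Ctrl H3K9me2 and 0.544 for CKO H3K9me2. It was 0.294 and 0.292 for the Ctrl inputs, 0.371 for the CKO input and 0.482 for H3K4me3.

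**Figure D1:**
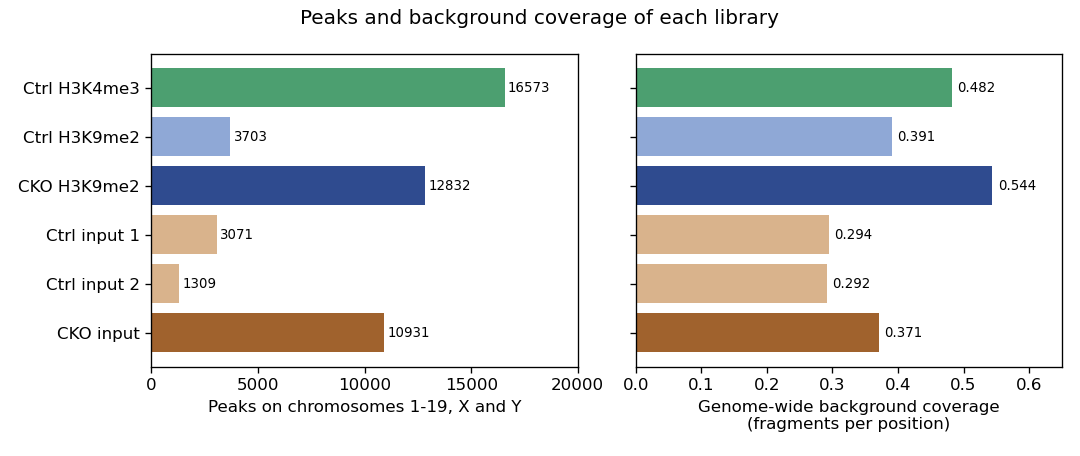
Number of peaks in each of the 6 lists (left, chromosomes 1 to 19, X and Y) and genome-wide background coverage of each library in fragments per position (right); each bar is 1 library. The CKO lists hold 12832 (H3K9me2) and 10931 (input) peaks, above 3703, 3071 and 1309 in the corresponding Ctrl lists, and their coverage is 0.544 and 0.371 against 0.391, 0.294 and 0.292.

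The targeted gene came first. Phf2 (chromosome 13, 48801750 to 48870885) carried an H3K4me3 peak at one end, at 48869852 to 48871516, with a fold of 7.81 in Ctrl. No peak lay in its body or within 2 kb of it in either H3K9me2 list or in the 3 input lists. H3K4me3 was mapped in Ctrl alone and peak lists do not show a deleted exon, so this does not check the knockout.

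The H3K4me3 list in Ctrl muscle addresses where active promoters lie. Its highest peaks at gene ends were those of Pacrgl (fold 25.7), 2610008E11Rik (25.2), Pnpt1, which encodes mitochondrial polynucleotide phosphorylase (25), Ndufb2, a subunit of respiratory complex I (24.5), Rwdd2b (24.3), Zkscan8 (24.3), Mtx3 (24.0), Lsm5 (23.9), Trdmt1 (23.8) and Hps3 (23.7). The Pnpt1 peak spanned 29130629 to 29131151 on chromosome 11 and the Ndufb2 peak 39592421 to 39592980 on chromosome 6. Of 21887 protein-coding genes, 13023 (59.5%) had an H3K4me3 peak within 2 kb of either end. Without strand, that end need not be the promoter, and the peak may belong to a neighbouring gene. Muscle growth and breakdown genes had such a peak almost throughout. Of 15 genes of atrophy and autophagy 14 did, led by Sqstm1 (fold 14.6), Bnip3 (13.6) and Eif4ebp1 (13.1). Of 15 genes of growth signalling 14 did, led by Igf1 (13.8), Mtor (13.5) and Akt2 (12.5). The Mtor peak lay wholly outside the gene.

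Among 10000 random lists matched on gene length, 0.50% reached the count of the atrophy list and 2.14% that of growth signalling. Oxidative metabolism had 14 of 16 genes with a peak (1.13% of random lists as high), including Ppard (fold 15.5), Tfam (13.1) and Pdk4 (12.9). Enzymes, readers and cofactors of H3K9 and H3K4 methylation had 21 of 22 (0.33%), with Setdb1 at 19.5, Suv39h1 at 17.1 and Kdm3a at 14.1, and the exception was Kdm4c. Housekeeping genes had 14 of 15 (0.40%), with Sdha at 18.1. Zinc finger genes named Zfp with a number had 305 of 367, above each of the random lists, with Zfp433 at 23.6 and Zfp748 at 23.2. In clusters of near-identical zinc finger genes, shared reads make the member uncertain.

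Several lists of other tissues and cell types lay below the random lists. The liver list had 1 of 12 genes with a peak (Apoa1, fold 5.40; 0.02% of random lists as low), the neuronal list 3 of 12 (0.51%), and fibroadipogenic markers 2 of 11 (Fbn1 at 13.7 and Col1a2 at 6.64; 0.10%). Blood and immune markers had 2 of 11 (Cd68 and Cd79a; 1.33%) and Schwann cell markers 2 of 8 (2.14%). Olfactory receptors had 2 of 1110 and vomeronasal receptors 3 of 355, below each of the random lists. Slow-fibre sarcomere genes were also below the random lists, with 2 of 12 (Tnnc1 at 15.9 and Atp2a2 at 6.88, 0.09%). The fast myosin genes Myh1, Myh2 and Myh4, named here after their values were seen, likewise had no peak at either end. A missing peak therefore does not show that a sarcomere gene is inactive. The peaks counted for Tnnc1, Cd68 and Cd79a lay wholly outside the gene.

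The remaining lists lay within the middle 95% of random lists. Fast-fibre sarcomere genes had 10 of 15, led by Tpm1 (8.94), Pvalb (8.71) and Actn3 (8.70), and sarcomere genes of all fibres 8 of 15, led by Myom1 (11.2) and Des (8.81). Myogenic regulators had 12 of 15, led by Eya1 (16.7) and Pax3 (10.7), with Myod1 at 8.95 and Myog at 7.91. Glycolysis had 11 of 12 (Pfkm 14.6), the neuromuscular junction 10 of 14 (Dok7 14.5), satellite cell markers 8 of 10 (Sdc4 9.59), endothelial markers 4 of 10 (Kdr 14.3), adipocyte markers 2 of 8 (Plin1 16.8) and imprinted genes 6 of 10 (Plagl1 15.4). In all, 6 of 23 lists lay above and 8 below, where 1.15 outside the middle 95% would arise by chance. Restricting to peaks at or above the median fold of the list left 2 lists above. The calls for growth signalling and Schwann markers ended under each of the 3 alternatives tried. That for atrophy and autophagy ended under 2 of them (7 of 15 genes with those peaks of higher fold and 12 of 15 within 1 kb). With the peaks of higher fold the calls for oxidative metabolism (6 of 16), housekeeping (8 of 15) and blood and immune markers (1 of 11) ended too. Within 5 kb that for neuronal genes (5 of 12) ended. With the peaks of higher fold, fast-fibre sarcomere genes (0 of 15), shared sarcomere genes (1 of 15) and satellite cell markers (0 of 10) fell below the random lists. Glycolysis (12 of 12) rose above the random lists within 5 kb. Fold is relative to local background, so a lower fold is not a lower summit. Tpm1 had 87 summit fragments at a fold of 8.94 and Smad7 124 at 4.65, where the list median was 52.

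**Figure D2:**
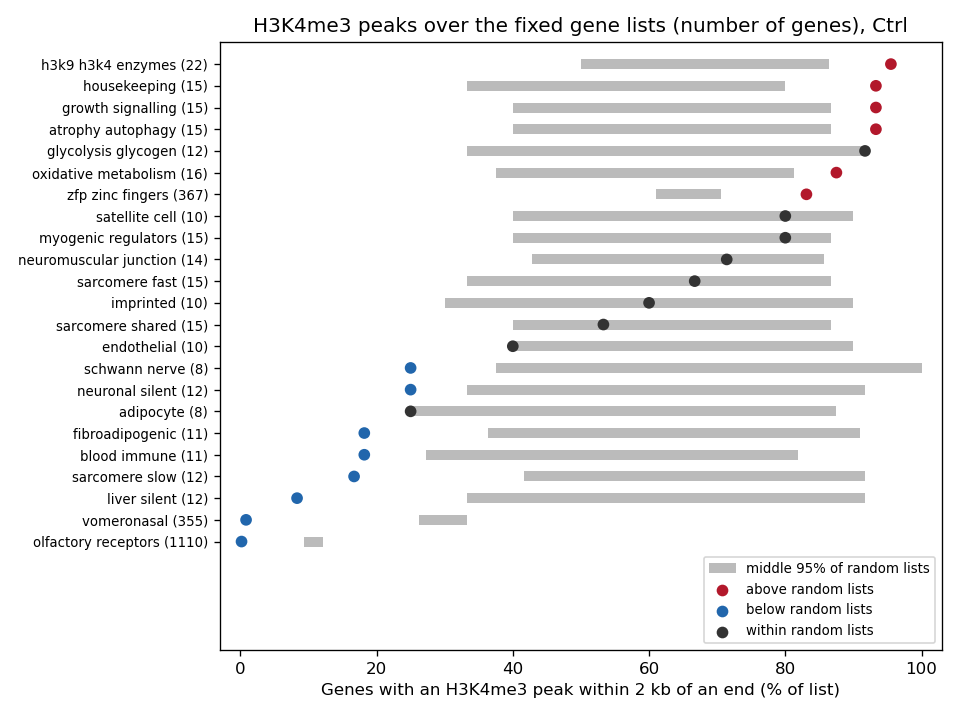
Share of each fixed gene list with an H3K4me3 peak within 2 kb of a gene end in Ctrl (points, 1 library; number of genes in brackets) beside the middle 95% of 10000 random lists matched on gene length (grey bars). Enzymes, readers and cofactors of H3K9 and H3K4 methylation (21 of 22), housekeeping, atrophy and growth genes lie above their bars, and olfactory (2 of 1110) and liver genes (1 of 12) below.

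The comparison of H3K9me2 between CKO and Ctrl asks where the mark is found with and without PHF2 in muscle fibres. Muscle tissue also holds other cell types, in which this Cre need not act, and the peak lists do not tell cell types apart. After peaks overlapping any input peak were removed, 9823 CKO and 2712 Ctrl peaks were left. Of these, 9093 were in the CKO list alone, 1982 in the Ctrl list alone and 730 in both. The highest peaks of the CKO list alone lay far from genes, at chromosome 13, 68428919 to 68429495 (fold 13.5, 131 kb from Mtrr), chromosome 5, 42323932 to 42324413 (13.2, 480 kb from Bod1l) and chromosome 13, 101039109 to 101039539 (12.5, 206 kb from Slc30a5). Of the 15 highest, those at genes were at the end of Rnpc3, a minor spliceosome gene (chromosome 3, 113629752 to 113630163, fold 12.5, also an H3K4me3 peak), in the body of Rundc3b (11.5) and in the body of Fgf14, a modulator of sodium channels (11.4).

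The highest peak of the Ctrl list alone was intergenic as well, at chromosome 14, 94548727 to 94549103 (fold 10.3, 656 kb from Pcdh9). It was followed by a peak in the body of Grik2, a kainate receptor gene (9.87, chromosome 10, 49444412 to 49444789). Further down were Nrsn1 (8.73, within 2 kb of the gene) and the body of Galntl6 (8.47). By the mean of both folds the highest shared peak, at chromosome 5, 15663761 to 15664200, had folds of 11.7 in CKO and 8.64 in Ctrl and lay 39.9 kb from Speer4d. A neighbouring shared peak at 15806972 to 15807315 had 8.28 and 9.89. Speer4 genes are near-identical copies, and whether the intergenic sequence at these peaks is also duplicated was not tested. Shared peaks in genes included Tmprss11a (9.20 in CKO and 8.23 in Ctrl) and Nlgn1, a synaptic adhesion gene (10.5 and 6.62).

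Random placement of the CKO peaks within their chromosomes gave a mean of 8.74 shared peaks and at most 20 in 1000 placements, against 730 observed. That was 83.5 times the mean, and an excess of this kind is not particular to the antibody. In whole lists, CKO H3K9me2 peaks overlapped Ctrl H3K9me2 peaks at 83.6 times the random mean, and Ctrl input 1 overlapped Ctrl input 2 at 234 times. The CKO input overlapped Ctrl inputs 1 and 2 at 121 and 131 times. The multiple depends on the chance share, which was 0.133% for CKO H3K9me2 in Ctrl and 0.0422% for Ctrl input 1 in input 2. The multiples therefore do not rank the lists, and by share the Ctrl inputs held 9.90% and 23.3% of each other. Before removal of input peaks, 38.4% of Ctrl peaks (exact 95% binomial interval 36.8 to 40.0) and 11.1% of CKO peaks (10.5 to 11.6) overlapped the other genotype. Absence from a list means that no peak passed the authors' threshold, which at a median of 6 fragments in Ctrl does not show absence of the mark. At q of 1e-05 or less the classes held 4470 CKO, 155 Ctrl and 135 shared peaks, and with both lists shortened to the same number of peaks they held 2415, 2415 and 297. Intervals cover counting error alone.

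The CKO lists were longer in H3K9me2 and in input alike. The CKO H3K9me2 list held 3.47 times as many peaks as the Ctrl list and covered 5690 against 1589 kb, with a background coverage 1.39 times as high. The CKO input list held 3.56 times as many peaks as Ctrl input 1 and 8.35 times as many as Ctrl input 2, at 1.26 and 1.27 times the coverage. Against the mean of both Ctrl inputs the ratio was 4.99, and it was 8.35 without Ctrl input 1. The 2 Ctrl inputs, of 1 genotype and nearly equal coverage, differed by 2.35 times in peak number. At q of 1e-05 or less the ratios were 12.9 for H3K9me2 and 7.73 for input.

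The input lists shared their strongest regions with each of the other lists. The highest region of each input list was at chromosome 9, 35305224 to 35305594, 29.3 kb from Rpusd4, with folds of 30.9 and 32.1 in the Ctrl inputs and 32.8 in the CKO input. The same region had folds of 27.7 and 30.3 in the H3K9me2 lists and 30.8 in the H3K4me3 list. Regions in the body of Zc3h7a (chromosome 16, 11143902 to 11144316), within Cmss1 and Filip1l (chromosome 16, 57391209 to 57391692), in Jarid2 (chromosome 13, 44869565 to 44869989), and intergenic at chromosome 3, 5860391 to 5860822 and chromosome 11, 109011646 to 109012104, were likewise in all 6 lists. Of the 1309 Ctrl input 2 peaks, 50 overlapped all 5 other lists.

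Against both Ctrl inputs, 9109 CKO input peaks were in CKO alone, 1822 were shared, and 2326 Ctrl input peaks were in Ctrl alone. Ctrl input 1 shared 9.90% of its peaks with Ctrl input 2, and Ctrl input 2 shared 23.3% with Ctrl input 1. The longer CKO input list held 46.0% and 48.9% of their peaks, which were 12.9% and 5.85% of its own. Without Ctrl input 1, the peaks in Ctrl alone fell to 669 and the shared CKO peaks to 640.

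Of H3K9me2 peaks, 23.4% in CKO (22.7 to 24.2) and 26.8% in Ctrl (25.3 to 28.2) overlapped at least 1 input peak. Random placement gave 0.462% and 0.457%. H3K9me2 peaks with an input peak overlapped an H3K4me3 peak more often than those without, at 38.7% against 6.39% in CKO and 33.7% against 5.46% in Ctrl.

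H3K9me2 peaks were also found at gene ends marked by H3K4me3 in Ctrl, the only genotype in which H3K4me3 was mapped. In CKO the peak at the end of Trim28, which encodes a corepressor that recruits H3K9 methyltransferases (chromosome 7, 13024084 to 13024508, fold 6.20), lay inside the H3K4me3 peak at 13023869 to 13025117. The same held at Irs1 (chromosome 1, 82290906 to 82291537, fold 4.42) and Zfp433 (chromosome 10, 81704803 to 81705133, 9.30) in CKO and at Igf1r (chromosome 7, 67952074 to 67952681, 4.21) in Ctrl. In the whole lists, 14.0% of CKO peaks (13.4 to 14.6) and 13% of Ctrl peaks (11.9 to 14.1) overlapped an H3K4me3 peak, 17.3 and 16.4 times the mean of random placements. Input peaks did so far more often, at 47.7% and 54.2% in Ctrl and 50% in CKO.

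Among H3K9me2 peaks without an input peak, the share with H3K4me3 was 6.39% in CKO (5.92 to 6.90) and 5.46% in Ctrl (4.63 to 6.38). These were 8.07 and 6.95 times the mean of random placements. Peaks in CKO alone had 6.35%, those in Ctrl alone 4.94% and shared peaks 6.99%. Conversely, 10.8% of H3K4me3 peaks (10.3 to 11.3) carried a CKO H3K9me2 peak and 32.7% (32.0 to 33.5) a CKO input peak. In Ctrl these shares were 2.91% for H3K9me2, 8.84% for input 1 and 4.28% for input 2.

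H3K9me2 peaks were mostly intergenic in both genotypes, H3K4me3 peaks mostly at gene ends, and input peaks in between. Peak centres in intergenic sequence made up 66.4% of Ctrl and 64.2% of CKO H3K9me2 peaks, where random placement gave 57.5% and 57.3%. They made up 11.4% of H3K4me3 peaks, 35.4% and 33.7% of Ctrl input peaks and 30.2% of CKO input peaks. Within 2 kb of a gene end lay 71.3% of H3K4me3 peaks, 12.8% of Ctrl and 14.2% of CKO H3K9me2 peaks, and 44.1% to 46.9% of input peaks. Random placement gave 5.64% and 5.65% for the H3K9me2 lists. Relative to it, H3K9me2 peaks were 2.27 (Ctrl) and 2.52 (CKO) times as frequent at gene ends. In intergenic sequence they were 1.16 and 1.12 times as frequent. Gene bodies held 20.8% of Ctrl and 21.5% of CKO H3K9me2 peaks, below 36.9% and 37.1% by random placement.

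**Figure D3:**
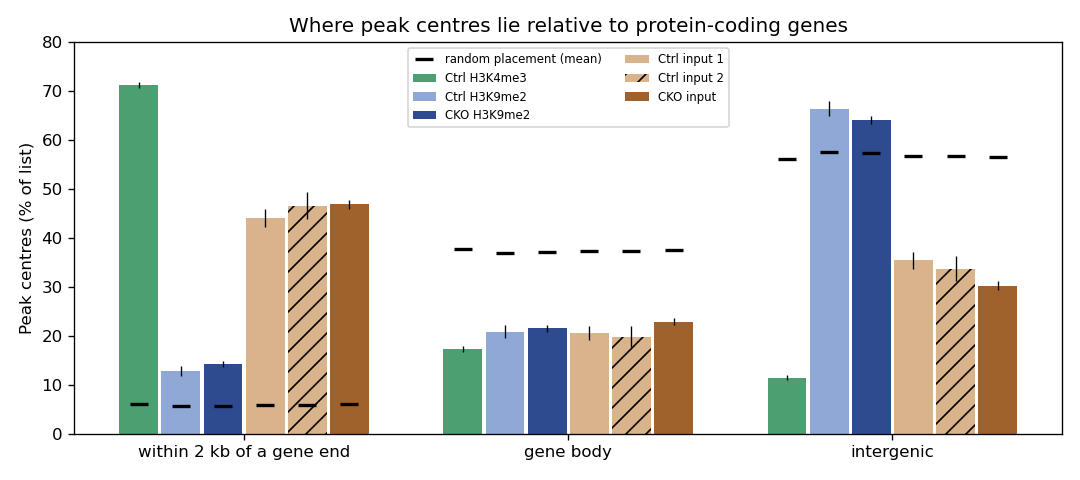
Share of peak centres of each list within 2 kb of a protein-coding gene end, in a gene body or in intergenic sequence (bars, in percent of the list, 1 library each; error bars, exact 95% binomial intervals), with the mean of 1000 random placements as black dashes. H3K9me2 peaks are intergenic in 66.4% (Ctrl) and 64.2% (CKO), and H3K4me3 peaks lie at gene ends in 71.3%.

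Autosomes rich in genes held fewer H3K9me2 peaks for their length. Chromosome 11, with 13.5 protein-coding genes per Mb, had 3.69 CKO and 1.03 Ctrl H3K9me2 peaks per Mb, the lowest of the 19 autosomes in both. Chromosome 3, with 6.26 genes per Mb, had the highest densities, 6.32 and 1.90. Chromosomes X and Y, of which males carry a single copy, had few genes (5.76 and 2.91 per Mb) and still fewer H3K9me2 peaks, 1.79 and 0.273 per Mb in CKO and 0.554 and 0.171 in Ctrl, and were not among the autosomes correlated. The other lists were sparse there too, so this is not particular to H3K9me2. H3K4me3 had 3.0 and 0.0455 peaks per Mb, the CKO input 1.26 and 0.421, Ctrl input 1 0.328 and 0.194, and Ctrl input 2 0.119 and 0.137. Over the 19 autosomes, peak and gene density were negatively correlated in CKO (Pearson r = -0.756, permutation p = 0.00017; Spearman rho = -0.693, permutation p = 0.0014, 0.0025 after Benjamini-Hochberg adjustment over the 6 lists). In Ctrl the values were r = -0.616 (permutation p = 0.0049) and rho = -0.505 (permutation p = 0.029, adjusted 0.035). Tests were two-sided.

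Input density rose with gene density in Ctrl input 1 (rho = 0.686, permutation p = 0.0017, adjusted 0.0025) and the CKO input (0.788, p = 0.00011, adjusted 0.00033), and the relation did not pass in Ctrl input 2 (0.349, p = 0.14, adjusted 0.14). Pearson r was 0.600 (permutation p = 0.0067) and 0.276 (p = 0.25) for Ctrl inputs 1 and 2 and 0.779 (p = 0.00014) for the CKO input. H3K4me3 followed gene density closely (rho = 0.932, p = 1e-05, the smallest that 100000 permutations can give, adjusted 6e-05; r = 0.910, p = 1e-05). Leaving out chromosomes 7 and 11, farthest from the median gene density, gave r of -0.625 (permutation p = 0.0072) and rho of -0.584 (p = 0.015) in CKO H3K9me2. In Ctrl H3K9me2 it gave r of -0.549 (permutation p = 0.022) and rho of -0.418 (p = 0.096), where r passed 0.05 and rho did not. Without them r was 0.581, 0.222 and 0.724 in the inputs and 0.939 for H3K4me3. In a comparison chosen after these values were seen, intergenic peaks per Mb of intergenic sequence were set against gene density. CKO H3K9me2 then gave r of -0.667 (permutation p = 0.0018) and rho of -0.433 (p = 0.067), and Ctrl H3K9me2 -0.420 (p = 0.075) and -0.323 (p = 0.18). Without chromosomes 7 and 11 the CKO values were -0.374 (permutation p = 0.14) and -0.211 (p = 0.41), and those of Ctrl -0.266 (p = 0.30) and -0.154 (p = 0.55).

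**Figure D4:**
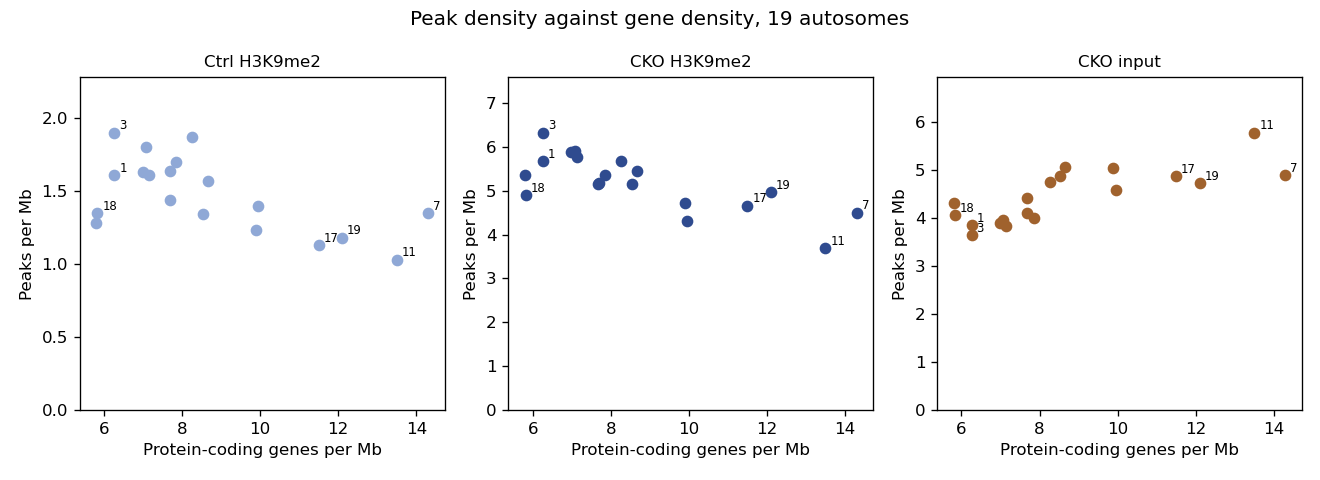
Peaks per Mb against protein-coding genes per Mb on the 19 autosomes (1 point each, some labelled by number) for Ctrl H3K9me2, CKO H3K9me2 and CKO input. Density falls with gene density for H3K9me2 (rho of -0.505 and -0.693) and rises for input (0.788).

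Of the genes in the fixed lists, few had an H3K9me2 peak in both genotypes. Myf5, a myogenic regulatory factor, had an input-free peak in CKO (chromosome 10, 107485499 to 107485935, fold 5.60) and an overlapping one in Ctrl (107485358 to 107485729, fold 6.17). Calcr, the calcitonin receptor of quiescent satellite cells, had one at a gene end in CKO (chromosome 6, 3687348 to 3687702, 8.06) and another in its body in Ctrl (3698689 to 3699033, 4.31). The macrophage gene Adgre1 had overlapping peaks in its body in CKO (7.36) and Ctrl (5.34). Other muscle genes had a peak in CKO alone: Myf6 (5.18), Sox6 (5.37), Tnnt3 (3.68), Myl1 (5.52), Myom2 (7.68), Ppargc1a, a regulator of mitochondrial biogenesis (5.80), and Irs1 (5.55 in its body). The Tnnt3 peak rested on 5 summit fragments and the Myf6 peak on 7, and both lay inside Ctrl H3K4me3 peaks. The other peaks of this group rested on 8 to 12 fragments.

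Counted over gene bodies with 2 kb either side, 2064 genes (9.43%) had an input-free H3K9me2 peak in CKO and 685 (3.13%) in Ctrl. They shared 380 genes, 1.65 times the mean of 230 when CKO genes were replaced by random genes of similar length (at most 276, a comparison chosen after the data were seen), and 1684 were in CKO alone and 305 in Ctrl alone. Satellite cell markers were above the random lists in both: 3 of 10 in CKO (Calcr, Myf5 and Chodl; 1.96% of random lists as high) and 2 of 10 in Ctrl (1.73%). Lists with 0 genes could not lie below the random lists, as at least 19.1% of random lists had 0 in CKO and 21.0% in Ctrl. Chance therefore gives at most 1.15 lists outside. The satellite cell call was 1 of 23 per genotype, which chance may give. The call ended in both genotypes with peaks at or above the median fold, without input removal, or with removal by the same genotype's input, and in CKO also with a 5 kb window. Among peaks of CKO alone, 0 of 23 lists stood apart.

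Counts in the other lists lay within the random range. In CKO, fast-fibre sarcomere genes had 2 of 15, shared sarcomere genes 1 of 15 and slow-fibre genes 0 of 12. Myogenic regulators had 3 of 15, neuronal genes 4 of 12 (Syt1 at 7.30, Gad1 at 6.98, Gad2 at 4.95 and Rbfox3 at 4.53) and imprinted genes 2 of 10 (Snrpn at 8.95 and Grb10 at 4.53). Histone methylation enzymes, readers and cofactors had 1 of 22, the corepressor gene Trim28. Oxidative metabolism (Ppargc1a), growth signalling (Irs1), fibroadipogenic (Col1a2), endothelial (Tek), blood and immune (Adgre1) and Schwann cell markers (Pmp22) had 1 gene each. The atrophy, glycolysis, neuromuscular junction, adipocyte, housekeeping and liver lists had 0. Olfactory receptors had 28 of 1110 (Olfr819 at 9.62), numbered Zfp genes 28 of 367 (Zfp959 at 9.46) and vomeronasal receptors 13 of 355 (Vmn2r86 at 7.15).

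In Ctrl, neuronal genes had 2 of 12 (Syt1 at 5.61 and Neurod1 at 4.44), and myogenic regulators, growth signalling (Igf1r) and blood and immune markers 1 each. Olfactory receptors had 9 of 1110 (Olfr1280 at 6.50), numbered Zfp genes 7 of 367 (Zfp386 at 6.57) and vomeronasal receptors 5 of 355 (Vmn2r26 at 6.65). With a 5 kb window the vomeronasal list rose above the random lists in Ctrl, with 10 genes. The other 15 lists had 0 genes in Ctrl. Input peaks lay near 33.2% of genes in CKO and 9.59% and 4.32% in Ctrl. In the CKO input, histone methylation enzymes, readers and cofactors were above the random lists (16 of 22, 0.76% as high). Liver genes, olfactory and vomeronasal receptors were below (0 of 12, 11 of 1110 and 7 of 355). Olfactory and vomeronasal receptors were also below in Ctrl input 1 (1 of 1110 and 2 of 355), and vomeronasal receptors in Ctrl input 2 (1 of 355).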

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

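The thinning to equal coverage was chosen after the data were seen, and the other alternatives before. No result reversed, but only the peak-number ratios and the calls for single gene lists could be scored as reversed. Counts and ratios held if within 1.5 times and shares if within their counting interval. By these rules 74 checks of the main results held and 55 moved. With peaks at or above the median fold of their list, H3K9me2 peaks numbered 1907 in Ctrl and 6426 in CKO, which follows from shortening the lists. In CKO alone, Ctrl alone and both there were 4871, 1061 and 430, and for input 4944, 1456 and 688. H3K9me2 peaks overlapped input in 17.5% (CKO) and 21.9% (Ctrl) and H3K4me3 in 9.76% and 9.49%. Gene ends held 83.5% of H3K4me3, 11.4% of Ctrl and 13.1% of CKO H3K9me2 peaks. Genes with a peak were 8137 for H3K4me3, 1224 for CKO and 392 for Ctrl H3K9me2, with 2, 0 and 0 gene lists above the random lists. At q of 1e-05 or less, H3K9me2 peaks numbered 392 in Ctrl and 5039 in CKO, classes 4470, 155 and 135, and the CKO to Ctrl ratios were 12.9 for H3K9me2 and 7.73 for input. Overlap of 50% of the shorter peak gave 21.8% (CKO) and 24.6% (Ctrl) with input, and a distance of 1 kb 24.6% (CKO). Without removal of input peaks, 1421 peaks were shared and 3367 CKO and 1129 Ctrl genes had one. Then, and with removal by the same genotype's input, 0 gene lists were above in either genotype. Leaving out either Ctrl input gave an input ratio of 3.56 to 8.35, input overlap of 20.7% to 22.7% (CKO) and 24.2% to 25.8% (Ctrl), 669 to 1657 input peaks in Ctrl alone and 640 to 1414 shared. With lists of equal length, 2415 H3K9me2 peaks were in CKO alone and 297 shared, and 3432 and 948 for input, which follows from the shorter lists. With 1 kb windows, gene ends held 64.9% of H3K4me3, 11.2% of Ctrl and 12.6% of CKO H3K9me2 peaks, and with 5 kb 77.4%, 15.7% and 17.4%, as the windows require. With 5 kb, 0 gene lists were above in CKO and 2 in Ctrl. Where construction does not account for a change, the cause was not tested. Over single gene lists, 19 calls were lost, 5 gained and 0 turned. Summits of 6 to 9 fragments limit H3K9me2: a peak missing from a list is not a measured absence. No paired analysis was possible because each H3K9me2 group holds 1 library and no test between groups was made.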

Other observations

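The thinned ratios for H3K9me2 and input, the share of CKO peaks also called in input and the comparison of H3K9me2 and input shares among H3K4me3 peaks are tests chosen after the result was seen, the thinned ones after the unthinned counts. The intergenic correlations are also tests chosen after the correlations over all peaks were seen, and the reading of the latter as undecided was settled after their values were seen. The bounds of the open-promoter test were set beforehand, but its reading per genotype, and as undecided in both, was settled after its values were seen. The genes named in the next paragraph were chosen after their values were seen.

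Several of the most abundant structural genes of muscle fibres had no H3K4me3 peak at either end. Of the 42 genes in the 3 sarcomere lists, 22 had none, and 14 of those had no H3K4me3 peak within 5 kb of the gene. They included the fast myosin genes Myh2, Myh1 and Myh4 (chromosome 11, 67171027 to 67260447 in all), whose nearest peaks were 118, 147 and 185 kb away. Also among them were skeletal actin Acta1 (8.24 kb), creatine kinase Ckm (6.71 kb), titin Ttn (28.1 kb) and nebulin Neb (63.1 kb). Of the 15 myogenic regulators 12 had a peak, among them Myod1, Myog and Pax7 (folds of 8.95, 7.91 and 5.49), while Myf5 (nearest 6.78 kb away), Mef2a and Mef2c had none at either end. Why these gene ends carry no called peak was not tested, and no genome sequence or expression table was used here.

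H3K9me2 and input peaks alike were more frequent at H3K4me3 peaks of higher fold over local background. Of the 4144 H3K4me3 peaks with the lowest folds, 3.60% (3.05 to 4.21) carried a CKO H3K9me2 peak and 11.5% (10.5 to 12.5) a CKO input peak. Of the 4143 with the highest folds, 14.5% (13.4 to 15.6) and 42.2% (40.7 to 43.7) did. For Ctrl H3K9me2 the shares were 0.917% (0.650 to 1.26) and 4.54% (3.92 to 5.22).

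The CKO H3K9me2 list is 3.47 times as long as the Ctrl list. Among peaks with 10 or more summit fragments and a local background up to 2 times the genome-wide one, the ratio was 17 (3407 against 200), and with CKO summits thinned to 71.9% of their fragments it fell to 4.86 (95% interval from Poisson counts 4.21 to 5.70), which argues against depth as the whole cause but not as a large part of it. Whether the added peaks are sites with input signal cannot be told apart from the calls: 20.4% (19.6 to 21.1) of the 11411 peaks absent from Ctrl, before removal of input peaks, overlapped an input peak, but input calls recur incompletely, with 9.90% and 23.3% of Ctrl input peaks shared between the Ctrl inputs and 46.0% and 48.9% found in the CKO input. A difference between the CKO and Ctrl preparations shared with input stays open, as the input ratio fell from 13.6 to 3.28 (2.42 to 4.69) against Ctrl input 1 and from 30.3 to 7.14 (4.78 to 12.2) against Ctrl input 2, and the Ctrl inputs themselves differed by 2.17 (1.33 to 3.86). A gain of H3K9me2 without PHF2, the difference the design names, also stays open and untested, because each genotype has 1 library.

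H3K9me2 peaks overlap H3K4me3 peaks 17.3 (CKO) and 16.4 (Ctrl) times as often as random placements. Enrichment of both marks at the same sites by the H3K9me2 antibody over input would give more H3K4me3 peaks with H3K9me2 than with input. The shares were lower: 10.8% had a CKO H3K9me2 peak and 32.7% a CKO input peak. In Ctrl 2.91% had an H3K9me2 peak and 8.84% and 4.28% an input peak. An input used as control could lower H3K9me2 calls at input sites, and whether one was used is not given. The folds argue against one of these inputs having been the control. At chromosome 9, 35305224 to 35305594, they were 27.7 and 30.3 in H3K9me2 and 30.9 to 32.8 in the inputs. In Zc3h7a they were 25.2 and 27.8 against 26.8 to 29.6. The shares still do not decide against such enrichment. Each H3K9me2 list is 1 library, the Ctrl inputs alone differed between 8.84% and 4.28%, and H3K4me3 was mapped in Ctrl alone. For fragments released from open promoters regardless of antibody, input-free H3K9me2 peaks overlapped H3K4me3 5.76 (CKO) and 3.89 (Ctrl) times as often as the highest random placement, and CKO passed the bound of 5 set to exclude this, which assumed no such fragments without an input peak. Input calls recur too little for that: the Ctrl inputs shared 9.90% and 23.3% of their peaks, the CKO input held 46.0% and 48.9% (46.2 to 51.6) of them, and they held 12.9% and 5.85% of its own. Open-promoter fragments and H3K9me2 itself therefore cannot be told apart in either genotype.

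H3K9me2 peaks are denser on autosomes with fewer genes, though chromosomes 12 and 18, with 5.80 and 5.83 genes per Mb, had 5.35 and 4.89 CKO and 1.28 and 1.35 Ctrl peaks per Mb. Spearman's rank correlation with gene density was -0.693 in CKO and -0.505 in Ctrl, and for intergenic peaks per Mb of intergenic sequence -0.433 (permutation p = 0.067) and -0.323 (p = 0.18). Whether the inputs share the tilt is not decided by their lowest rho over all peaks, 0.349 (p = 0.14), because 44.1% to 46.9% of input peaks lie at gene ends, so the bound of 0 set beforehand did not test background between genes. Intergenic peaks gave 0.446 in the CKO input (permutation p = 0.057), -0.0228 in Ctrl input 1 (p = 0.93) and 0.196 in Ctrl input 2 (p = 0.42), short of the threshold in each. A placement of H3K9me2 by gene density and a background shared with input therefore cannot be told apart, and base composition and mappability were not tested.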
